A study of Homo sapiens with 442 samples.

How the data were processed

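The series holds 442 libraries from 38 lung tissue specimens, 20 labelled non-neoplastic and 18 labelled tumor, in 6 assays: Smart-seq2 RNA sequencing and MOWChIP-seq for H3K27ac, H3K4me1, H3K4me3, H3K27me3 and H3K9me3. Each specimen has 2 libraries per assay. Groups follow the tissue labels. Of the specimen numbers, 8 are carried by both a tumor and a non-neoplastic specimen; the labels do not say that such specimens share a donor, so they were treated as independent, and as blocks only in an alternative. No sequencing batch or date was used. Specimens were renamed N1 to N20 and T1 to T18.

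The authors deposited RNA counts, whole numbers of reads per gene symbol and library; their notes name Trim Galore and STAR with hg19, and the counting tool, the gene annotation and the strand setting are not given in the sources used here. For H3K27ac, H3K4me1 and H3K4me3 the authors deposited peak lists made with BWA 0.7.17 and MACS2 2.2.7.1, with a fold enrichment (a ratio) and the -log10 p and -log10 q of each peak. For H3K27me3 and H3K9me3 the authors deposited region lists laid out as those of HOMER, with the normalized tag signal of each region, its ratio over control and its p value. The region lists carry no q, and the control used for the peak lists is not given in the sources used here.

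RNA totals ran from 4681787 to 32219132 counts per library, which sets the precision of low values; intervals of that kind cover counting error only, and reads without molecular identifiers are not independent molecules. The read depth behind the peak lists is unknown. Of 55765 symbols in the files, 32692 matched the reference gene names, 2191 of them by a synonym. XIST, TSIX and genes of chromosome Y (411 genes) were left out of every table. Reads shared between paralogs (SFTPA1 and SFTPA2, keratins, GAPDH and its pseudogenes) and the variable HLA genes cannot be resolved from gene counts, and neither can antisense genes such as AFAP1-AS1 while the strand setting is not known.

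The counts of the 2 libraries of a specimen were summed. Genes were filtered with filterByExpr, which left 20544, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood fits (glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05. CPM values use the TMM-scaled totals. The rule for named genes took up to 10 protein-coding genes per direction with the largest fold change among those past the threshold, with a mean log2 CPM of at least 3 and the same direction in all 8 shared specimen numbers, plus members of the gene lists; 0 genes met it beyond the lists. The 38 gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01, where at least 4 genes were tested (35 lists), then with a correlation estimated per list and with fry. The gene lists, the tests, the rules for naming and most alternatives were fixed before the data were examined.

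Peaks and regions on autosomes were merged per library for covered lengths, combinations and bins. Peak numbers, and the choice of equal numbers of top-ranked peaks, took every chromosome in the lists, X included. A specimen's covered length and peak number were the means of its 2 libraries, and a combination of marks was counted where both libraries of the specimen had each mark. Bins of 1 kb (5 kb for H3K27me3 and H3K9me3) counted as marked where peaks covered at least 50% of the bin in both libraries; bins marked in at least 5 specimens and lacking the mark in at least 5 were tested with a two-sided Fisher's exact test. For each mark the 3 bins of smallest p per direction, at least 100 kb apart, were listed, and the first of either direction is printed. Lengths, peak numbers and RNA quality measures were compared with two-sided permutation tests of the difference of means, 100000 resamples; p was adjusted over 10 tests of numbers and lengths and over 4 tests of combinations, and left unadjusted for RNA quality. Computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

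Similarity between specimens was the correlation of log2 CPM over the 5000 most variable genes for RNA and the Jaccard index of marked bins for each mark. Similarities of 2 assays were compared by Spearman correlation with 10000 permutations of the specimens. Covered lengths were correlated with the mean log2 CPM of each list (175 relations) and with each other and with the overlap of the 2 libraries of a specimen (15 relations), by Pearson and Spearman with permutation p. These similarities, correlations and the ranges of lineage genes were chosen after the data were seen.

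Alternatives replaced edgeR by DESeq2 1.42.0, TMM by DESeq2 size factors, the filter by none, the sum by R1 or R2 alone, and added a minimum absolute log2 fold change of 1; they also took stricter peaks (-log10 q of at least 5, or 6-fold over control), equal numbers of top-ranked peaks, equal covered length of top-ranked H3K27ac peaks, other overlaps, 4 times larger bins, and subsets of specimens. The RNA test was also run on simulated data with 200 changed genes: it recovered 40% of genes changed 2-fold and 78% of genes changed 4-fold, with 2 unchanged genes called. The bin test was checked on simulated bins, and 200 simulated interval pairs matched a brute-force count. A planned comparison of promoter marks of genes with changed RNA was not made, because gene positions for hg19 were not used here.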

Results

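Lung tissue specimens labelled tumor (18 specimens, described in the series as non-small cell lung adenocarcinoma) or non-neoplastic (20 specimens) were profiled for RNA by Smart-seq2 and for 5 histone marks by MOWChIP-seq, a microfluidic form of chromatin immunoprecipitation sequencing. Each specimen had 2 libraries per assay, 442 libraries in all, and the specimen was the replicate. H3K4me3 was measured in 31 specimens (14 labelled tumor, 17 labelled non-neoplastic) and every other assay in all 38. RNA libraries held 4681787 to 32219132 counts (median 9668794), with 5559767 to 26171239 in the non-neoplastic group and the full range in the tumor group. The median number of peaks or regions per library was 90976 for H3K27ac, 135402 for H3K4me1, 36719 for H3K4me3, 31295 for H3K27me3 and 54667 for H3K9me3. The read depth behind the peak lists is unknown. Specimens are named N1 to N20 and T1 to T18 here.

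The first comparison asked which genes differed in RNA between tumor-labelled and non-neoplastic-labelled lung. P2RY6, a cell surface receptor for the nucleotide UDP, rose in the tumor group by a log2 fold change of 1.78 (SE 0.32), with 21.2 ± 17.6 CPM (counts scaled to the library total; SD, n = 18) against 6.15 ± 3.55 (n = 20), and 11 tumor specimens lay above the highest non-neoplastic one. CHGB, which encodes chromogranin B of neuroendocrine secretory granules, also rose (log2 fold change 7.62, SE 1.48), from 0.946 ± 1.13 to 185 ± 776 CPM, but specimen T4 alone held 3295 CPM and the tumor median was 0.662 CPM. Without T4 the log2 fold change of CHGB was 1.21 with an adjusted p of 0.829. ZFYVE9, an adaptor of TGF-beta receptor signalling, fell by 1.06 on the log2 scale (SE 0.21), to 2.26 ± 0.699 CPM from 4.70 ± 2.17 CPM, and 13 non-neoplastic specimens lay above the highest tumor one. AC105206.1, a transcript without a reference gene name, fell by 3.93 on the log2 scale (SE 0.75), with medians of 0.201 CPM in tumor and 1.08 CPM in non-neoplastic specimens.

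These 4 genes, 2 higher and 2 lower, were all that passed an adjusted p of 0.05 in edgeR among 20544 genes tested, each with an adjusted p of 0.0399. None met every part of the rule for naming (protein-coding, a mean log2 CPM of at least 3, and the same direction in all 8 specimen numbers carried by both a tumor and a non-neoplastic specimen), so they were chosen for naming after their values were seen. At an unadjusted p under 0.05, 622 genes were higher and 992 lower in edgeR (7.86% of the genes tested). Of 100 splits of the specimens into groups of the same sizes, the real one included, 44 gave at least 1614 such genes, the real number. The median of the other splits was 1527, so chance was not excluded for this number. DESeq2 called 47 genes higher and 74 lower, with 1183 and 1731 at an unadjusted p under 0.05, and its calls held 3 of the 4 edgeR genes, all but CHGB. Every one of the 4 calls ended in some of the 38 fits that left out 1 specimen: P2RY6 was called in 20 of them, AC105206.1 in 17, CHGB in 13 and ZFYVE9 in 13. The label took a median of 1.24% of the variance of a gene, and the share that a random label would take was not computed. The biological coefficient of variation between specimens, a spread relative to the mean and not a share of variance, was 75.3%.

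Gene lists fixed for cell types and pathways of the lung gave a broader view: by camera with its preset correlation, the genes of alveolar type 1 cells, endothelial cells and macrophages fell as lists and lung adenocarcinoma-associated genes rose. None of these 4 calls was kept with a correlation estimated per list (adjusted p = 0.435 to 0.573). The alveolar type 1 list, markers of the flat cells that line the gas-exchange surface, had negative fold changes in 8 of 10 tested genes and a median log2 fold change of -1.38 (camera adjusted p = 7.28e-07; adjusted p = 0.435 with an estimated correlation). Of its genes, 7 passed when adjusted over the list alone, all lower, and 0 over all genes. Among those 7, EMP2, a membrane protein of the tetraspan family, changed by -1.45 (SE 0.50), from 918 ± 860 to 336 ± 477 CPM, and CAV1, the main protein of caveolae, by -1.61 (SE 0.61), from 1113 ± 1088 to 364 ± 629 CPM. HOPX of the same list was at 473 ± 325 CPM in tumor and 435 ± 327 CPM in non-neoplastic specimens. All 14 endothelial genes had negative fold changes (median -0.91; camera adjusted p = 6.84e-08; adjusted p = 0.573 with an estimated correlation), although 0 passed either over all genes or adjusted over the list alone. CDH5, the cadherin of endothelial junctions, was at 17.8 ± 24.2 CPM in tumor and 39.6 ± 35.3 CPM in non-neoplastic specimens. All 11 macrophage genes were negative as well (median -0.92; camera adjusted p = 1.31e-05; adjusted p = 0.573 with an estimated correlation). In that list 3 genes passed adjusted over the list alone and 0 over all genes: FABP4, a fatty acid carrier (-2.56, SE 0.87), PPARG, a lipid-sensing nuclear receptor (-1.84, SE 0.63), and MCEMP1, given in the files as C19orf59 (-2.47, SE 0.80).

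Immediate early genes, which respond within minutes to stimulation or handling of a tissue, were negative in 12 of 12 members and fell as a list (median -0.59; camera adjusted p = 0.000652; adjusted p = 0.732 with an estimated correlation). FOSB, a member of the AP-1 transcription factor family, was at 26.0 ± 35.5 CPM in tumor and 103 ± 215 CPM in non-neoplastic specimens, and 0 genes of the list passed over all genes or adjusted over the list alone. The list was no longer called (adjusted p = 0.149) without the 4 specimens of low library correlation or high mitochondrial share.

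**Figure D1:**
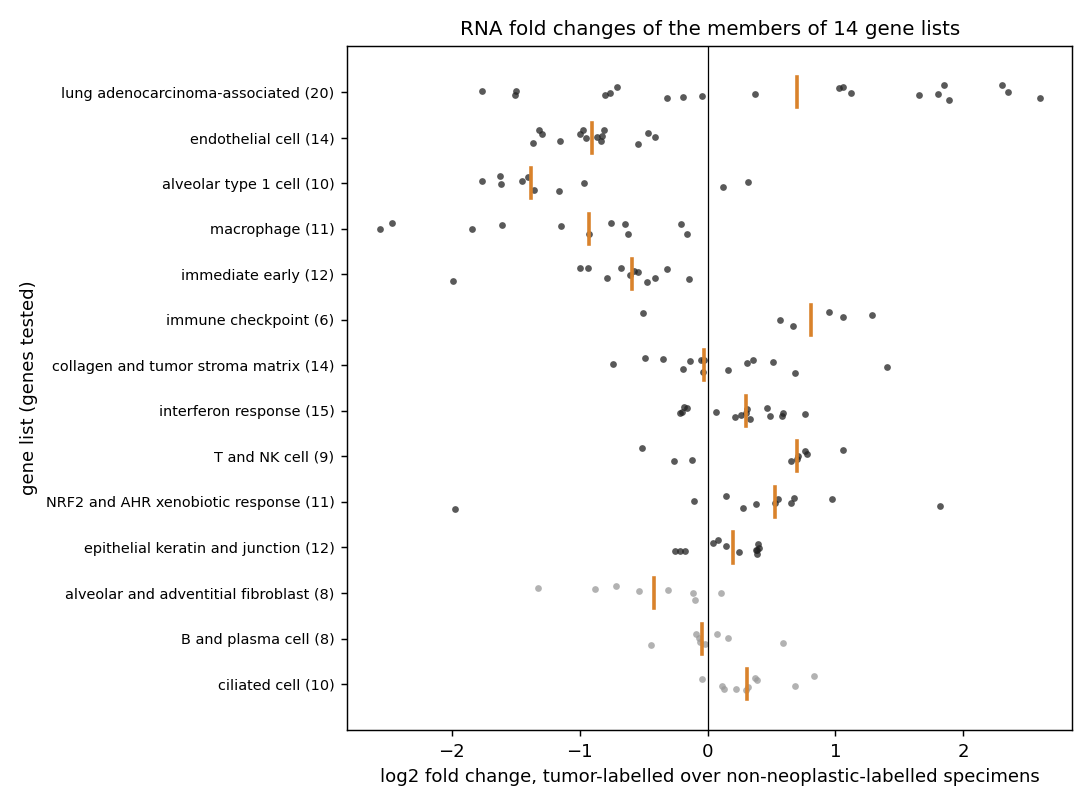
Log2 fold change (x axis) of each tested gene of 14 gene lists (y axis, number of genes tested in brackets); dots are genes, vertical marks are medians, and black dots belong to the 11 lists called by camera with its preset correlation. The endothelial, macrophage and immediate early genes all lie below 0, while the lung adenocarcinoma-associated list holds 11 positive and 9 negative genes.

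The lung adenocarcinoma-associated list, genes known from earlier work to be raised in such tumors, rose as a list although its members went both ways, with 11 positive and 9 negative fold changes (median 0.70; camera adjusted p = 4.47e-09; adjusted p = 0.435 with an estimated correlation). CRABP2, a retinoic acid carrier (2.35, SE 0.65), and HS6ST2, a heparan sulfate 6-O-sulfotransferase (2.30, SE 0.68), were the 2 genes that passed adjusted over the list alone, beside 0 over all genes in edgeR, and DESeq2 called both over all genes. CRABP2 stood at 75.1 ± 95.3 CPM in tumor and 14.7 ± 27.1 CPM in non-neoplastic specimens, and HS6ST2 at 31.7 ± 32.1 and 6.42 ± 7.07 CPM. CEACAM5, a cell surface glycoprotein of the same list, had a log2 fold change of -0.80 (SE 0.99), with 329 ± 583 CPM in tumor and 574 ± 1611 CPM in non-neoplastic specimens. That mean followed N19 and N20 at 6388 and 3839 CPM (the next non-neoplastic specimen was at 448 CPM), while the medians were 86.5 CPM in tumor and 24.9 CPM in non-neoplastic specimens. Immune checkpoint genes rose as a list (5 of 6 positive, median 0.81; camera adjusted p = 0.00238; adjusted p = 0.455 with an estimated correlation). TIGIT (1.06, SE 0.37) and CTLA4 (1.29, SE 0.46), inhibitory receptors of T cells, passed adjusted over the list alone, and 0 genes of the list passed over all genes. CD274, which encodes PD-L1, had a log2 fold change of -0.50 (SE 0.41).

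The other 5 lists that rose each had an adjusted p of 0.732 with an estimated correlation. They were T and NK cell genes (median 0.70, camera adjusted p = 0.0313), NRF2 and AHR xenobiotic response genes (0.53, 0.0313), interferon response genes (0.30, 0.0313), epithelial keratin and junction genes (0.20, 0.0463) and collagen and tumor stroma matrix genes (-0.03, 0.0203). In the collagen list the test and the mean (0.10) were positive while the median was negative. Without the 4 specimens of low library correlation or high mitochondrial share only the collagen list among these 5 was still called (adjusted p = 0.00771), against 0.0720 for T and NK cell, 0.0834 for epithelial keratin and junction and 0.592 for NRF2 and AHR genes, with interferon response genes between the last 2. None of these 5 lists held a gene that passed over all genes or adjusted over the list alone. CD2, an adhesion receptor of T cells, was at 26.6 ± 29.1 CPM in tumor and 12.8 ± 9.12 CPM in non-neoplastic specimens.

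In all, camera with a preset correlation of 0.01 called 11 of 35 lists, 4 lower and 7 higher, and 0 lists with a correlation estimated per list (3 at an unadjusted p under 0.05). The rotation test fry also called 0 lists (3 at an unadjusted p under 0.05). Over all genes 0 of the 370 list members tested passed in edgeR, where 20 were higher and 36 lower at an unadjusted p under 0.05. Of these 370, DESeq2 called 2 higher and 0 lower. Among list genes that the edgeR filter had left out, DESeq2 called DSG3 of the basal cell list lower (log2 fold change -6.93, adjusted p = 0.00104). It also called HOXA9 of the HOX list lower (-2.79, adjusted p = 0.0306). No difference in RNA quality between the labels passed its test: the correlation between the 2 libraries of a specimen had a median of 0.986 (permutation p = 0.318 between labels), and the share of mitochondrial counts a median of 12.7% (range 7.25 to 57.4%, p = 0.745). Without the 4 specimens of low library correlation or high mitochondrial share, 0 genes passed and 7 lists were called, among them 6 of the 11.

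Among the 24 lists that were not called, 5 held genes that passed adjusted over the list alone. Basal cell genes (adjusted p = 0.612) had 3 such genes, all lower: KRT5 (-5.19, SE 1.53), KRT17 (-2.97, SE 1.08) and TP63 (-2.04, SE 0.82), keratins and a transcription factor of basal and squamous epithelium. The KRT5 and TP63 differences followed a few specimens: N16 and N18 held KRT5 at 6175 and 3987 CPM, the next non-neoplastic specimen 146 CPM and the highest tumor specimen 114 CPM, and TP63 at 81.4 and 170 CPM, the next non-neoplastic specimen 11.3 CPM. KRT17 reached 13858 CPM in a non-neoplastic specimen. The medians of all 3 genes were higher in tumor than in non-neoplastic specimens (KRT5 3.32 and 0.614 CPM, KRT17 53.6 and 34.9 CPM, TP63 2.45 and 1.88 CPM). The other 4 were mast cell (KIT 1.76, SE 0.53; list adjusted p = 0.502), glycolysis (SLC2A1 -2.45, SE 0.81; 0.880), epithelial-mesenchymal transition (SNAI2 -1.80, SE 0.61; 0.551) and HOX (HOXD1 1.68, SE 0.54; 0.992). Alveolar type 2 cell genes were not called (adjusted p = 0.458): SFTPC, surfactant protein C, was at 4081 ± 6897 CPM in tumor and 30732 ± 38798 CPM in non-neoplastic specimens (log2 fold change -2.91, SE 1.09), while NAPSA, a protease that matures surfactant, was at 0.70 (SE 0.70). The lists nearest to a call were alveolar and adventitial fibroblast (adjusted p = 0.0754, median -0.42), B and plasma cell (0.0845), ciliated cell (0.0876, 9 of 10 genes positive), club and secretory cell (0.117), lung lineage transcription factor (0.133) and MHC class II presentation (0.133, 7 of 7 genes positive). Farther off lay mesothelial cell (0.358), mitosis and cell cycle (0.374), H3K9 methylation (0.502), DNA methylation (0.502), histone acetylation (0.555), mitochondrially encoded (0.555), H3K4 methylation (0.759), DNA replication (0.840), monocyte and neutrophil (0.880), Polycomb and H3K27 methylation (0.880), smooth muscle and pericyte (0.880) and MHC class I presentation (0.964). The erythroid and nuclear retained RNA lists had 3 and 2 tested genes, too few for the test, with median log2 fold changes of -0.94 and 0.27, and 0 cancer-testis genes were expressed enough to be tested. The direction of the test differed from that of the median or the mean in 10 lists: the collagen, club, monocyte, B cell, smooth muscle, mitosis, DNA replication, HOX, Polycomb and MHC class I lists.

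Levels of lineage genes spread widely within each label. SFTPC had a median of 14650 CPM in the non-neoplastic group, but 5 of its 20 specimens lay below the tumor median of 288 CPM and 9 lay above the highest tumor specimen. NKX2-1, the transcription factor that specifies lung epithelium, had medians of 31.0 CPM (non-neoplastic) and 37.3 CPM (tumor), and 3 specimens labelled non-neoplastic (N16, N18 and N20) lay below the lowest tumor specimen at 1.13 CPM. VIL1 and CDH17, genes of intestinal epithelium, reached 571 and 246 CPM in non-neoplastic specimens, of which 4 (VIL1) and 3 (CDH17) lay above the highest tumor values of 5.79 and 3.71 CPM. MKI67, a marker of dividing cells, had medians of 4.46 and 6.59 CPM in non-neoplastic and tumor specimens and maxima of 41.0 and 93.1 CPM.

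**Figure D2:**
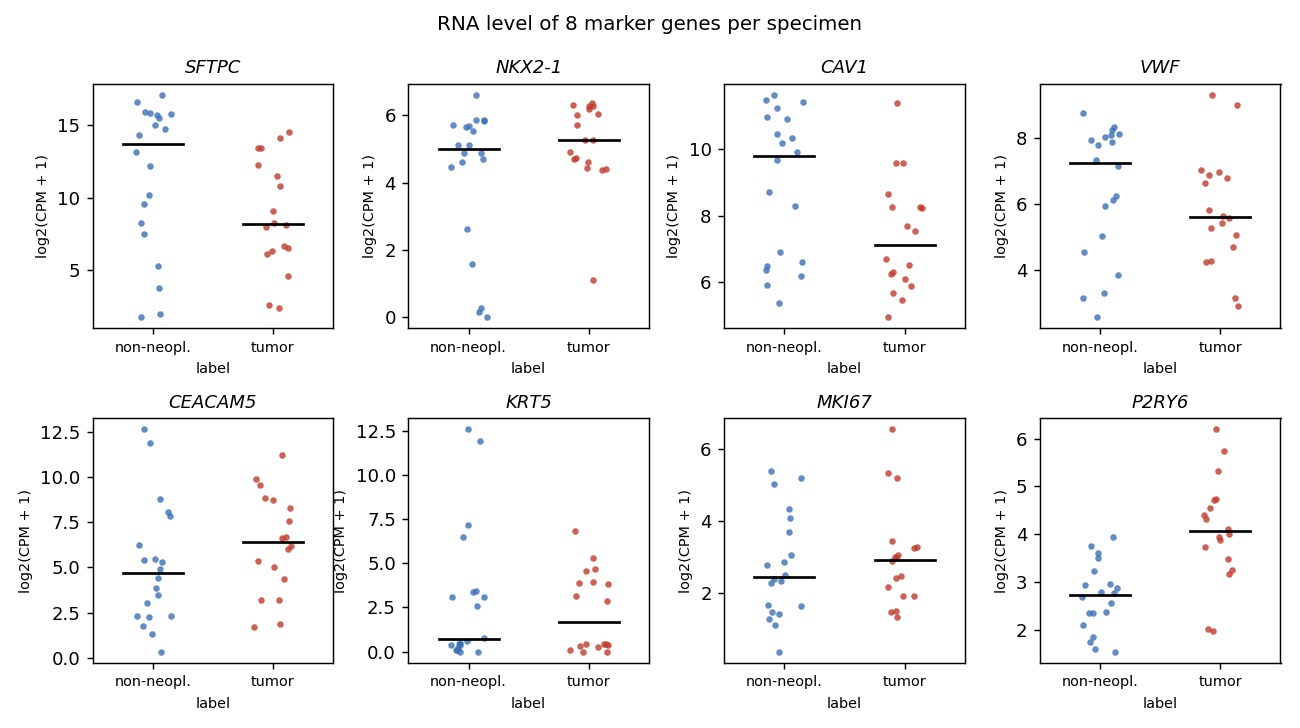
RNA level as log2(CPM + 1) (y axis) of 8 genes in each specimen, by label (x axis, points spread sideways for visibility); each dot is a specimen (20 labelled non-neoplastic, 18 labelled tumor) and the bar is the median. P2RY6 has 11 tumor specimens above the highest non-neoplastic one, whereas NKX2-1 and SFTPC reach their lowest values in specimens labelled non-neoplastic.

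The second comparison asked whether the amount of each histone mark differed. H3K27ac, a mark of active promoters and enhancers, covered 92.0 ± 20.0 Mb of the autosomes in tumor specimens (SD, n = 18) and 85.9 ± 25.7 Mb in non-neoplastic specimens (n = 20). H3K4me1, found at enhancers, covered 114 ± 29.6 and 108 ± 30.6 Mb, and H3K4me3, found at active promoters, 42.8 ± 5.21 (n = 14) and 41.4 ± 8.39 Mb (n = 17). Of the repressive marks, Polycomb-linked H3K27me3 covered 79.4 ± 40.8 and 77.7 ± 40.1 Mb, and heterochromatic H3K9me3 114 ± 32.1 and 114 ± 26.1 Mb. H3K27me3 varied most between specimens, from 18.2 to 205 Mb, an 11.2-fold range. Its lower end rested on N8 alone, since the next specimen, T17, had 33.0 Mb. All these differences were smaller than the spread between specimens, and none of the 10 two-sided permutation tests of covered length and peak number passed (adjusted p = 0.974 for each).

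**Figure D3:**
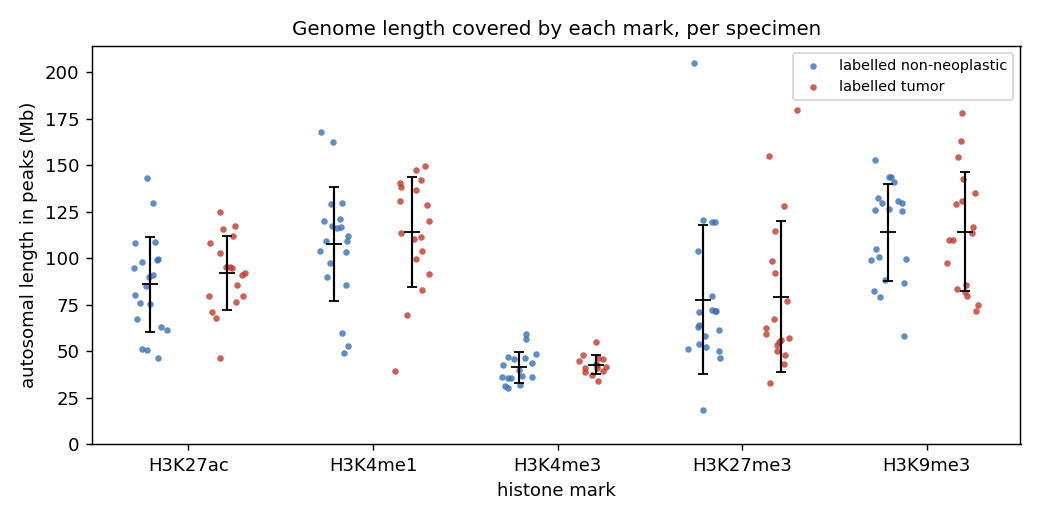
Autosomal length covered by peaks of each mark in megabases (y axis), by mark (x axis) and label (color); dots are specimens, and bars are the mean and 1 SD. The groups overlap for every mark, and H3K27me3 has the widest range, 18.2 to 205 Mb.

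Combinations of marks within the same specimen were compared next, in the 14 tumor and 17 non-neoplastic specimens with all 5 marks. Active promoter-like sequence, with H3K4me3 and H3K27ac, covered 21.0 ± 3.48 Mb in tumor and 19.3 ± 6.96 Mb in non-neoplastic specimens. Active enhancer-like sequence, with H3K27ac and H3K4me1 outside H3K4me3, covered 31.9 ± 10.9 and 27.1 ± 14.3 Mb. Bivalent sequence, with H3K4me3 and H3K27me3, covered 1.40 ± 0.445 and 1.43 ± 0.916 Mb, and sequence with both H3K27me3 and H3K9me3 covered 1.73 ± 0.941 and 2.19 ± 1.18 Mb. None of the 4 permutation tests passed (adjusted p = 0.534 to 0.955).

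The last comparison of labels looked for genome positions marked in more tumor or more non-neoplastic specimens. The H3K27ac bin with the smallest p, at 133237001 to 133238000 of chromosome 2 (hg19), was marked in 16 of 18 tumor and 4 of 20 non-neoplastic specimens (Fisher's exact p = 2.36e-05, adjusted p = 0.558). For H3K4me1, the bin at 55385001 to 55386000 of chromosome 5 was marked in 13 of 18 and 1 of 20 specimens (adjusted p = 0.607), and for H3K4me3, the bin at 128828001 to 128829000 of chromosome 7 in 14 of 14 and 6 of 17 (adjusted p = 0.984). The H3K27me3 bin at 81905001 to 81910000 of chromosome 14 was marked in 12 of 18 and 1 of 20 specimens, and the H3K9me3 bin at 78290001 to 78295000 of chromosome 3 in 0 of 18 and 12 of 20 (adjusted p = 1 for both). Fisher's exact test with Benjamini-Hochberg adjustment called 0 bins for any mark. At an unadjusted p under 0.05, 8292 H3K27ac bins were marked more often and 861 less often in tumor specimens, of 125110 tested. The counts were 10103 and 1647 for H3K4me1 (of 162138), 1062 and 121 for H3K4me3 (of 25527), 269 and 322 for H3K27me3 (of 15739), and 117 and 616 for H3K9me3 (of 18888). These leans depended on the specimens taken: outside the 8 shared specimen numbers the counts were 4099 and 2649 for H3K27ac, 5089 and 3919 for H3K4me1, 301 and 237 for H3K4me3, 220 and 350 for H3K27me3, and 21 and 831 for H3K9me3. Within those 8 numbers they were 1013 and 2, 885 and 8, 162 and 3, 16 and 20, and 33 and 23 in the same order of marks. Over all specimens of a mark, 100 splits into 2 groups, the real one included, were compared by the difference between the 2 counts. It was at least as large as the real one in 5 splits for H3K27ac, 7 for H3K4me1, 19 for H3K4me3, 84 for H3K27me3 and 31 for H3K9me3. A chance lean was thus not excluded for any mark. In simulated data with 200 changed bins per mark, the same test recovered 90% to 98.5% of bins marked in 95% of one group and 15% of the other. Differences of that size were within reach where as many bins changed together. Recovery of a single changed bin was not simulated. What genes lie at these bins is not given here, since no gene positions for hg19 were used.

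Similarity between specimens was then compared across assays. Specimens alike in RNA were also alike in their marks: the Spearman correlation of specimen similarities with RNA was 0.634 for H3K27ac, 0.536 for H3K4me1, 0.444 for H3K4me3, 0.384 for H3K27me3 and 0.346 for H3K9me3 (one-sided permutation, adjusted p = 0.00015 to 0.000577 for these 5 of the 15 assay pairs tested, where 0.0001 is the smallest p that the permutations can give). Between marks the highest value was 0.858, for H3K27ac with H3K4me1. By contrast, greater closeness of specimens within labels than between them did not pass a one-sided permutation test in any assay. The adjusted p of this test ran from 0.166 to 0.763 over 6 assays. In RNA the mean correlation was higher within labels by 0.00985, and for 23 of 38 specimens the nearest other specimen had the same label. That difference came from the tumor group: the mean RNA correlation was 0.604 within tumor, 0.567 within non-neoplastic and 0.573 between labels. For H3K27ac, H3K4me1 and H3K4me3 the non-neoplastic group also lay below the value between labels. For H3K27me3 and H3K9me3 it was the tumor group that lay below.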

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

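The tests chosen only after the result was seen were the fits without specimens of doubtful RNA quality, the fits that left out each specimen in turn, the stricter thresholds for H3K27me3, H3K9me3 and the combinations, the equal covered length for H3K27ac, the gene lists in the 8 shared specimen numbers with no replicate block, and the splits of the specimens for genes and bins. For RNA genes, DESeq2 in place of edgeR gave 47 higher and 74 lower, and no low-count filter gave 96 and 270, all 4 reported genes among them. Library R1 only gave 1 and 0 genes, and library R2 only gave 0 and 0. With the 8 shared specimen numbers as a replicate block, 0 genes were higher and 0 lower, as in the same specimens with no replicate block (0 and 0); only specimens outside the 8 shared numbers gave 3 higher and 1 lower, of which P2RY6 is also in the reported result. A check of the pairing was mixed: the correlation of deviations exceeded 0.1 for 4 of the 8 numbers (range -0.13 to 0.60) and 2 had their best match in their own number. Without specimens of low library agreement or high mitochondrial share, 0 genes were higher and 0 lower. Leave-one-out fits ranged from 0 to 7 genes higher and from 0 to 11 lower, with the highest of both without N1; only the fit without T5 moved neither count by more than 1.5 times. The causes of these shifts were not tested. Size factors in place of TMM, and an added fold threshold, gave 2 and 2.

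Gene lists called numbered 11 as reported, 0 with the correlation estimated per list, 15 with the replicate block for the 8 numbers (8 of the 11 among them) and 7 without specimens of low library agreement or high mitochondrial share. The same 16 specimens with no replicate block gave 12 lists, all among the 15 and 7 of them among the 11. Most of the rise in number from 11 to 15 thus came with the block, whereas the change in which lists were called came mostly with the choice of specimens. Lists called in these specimens both ways, but not as reported, were alveolar type 2 (adjusted p = 0.000245 without and 2.17e-07 with the block, against 0.458 as reported), mitosis, ciliated, lung lineage transcription factor and glycolysis, while T and NK cell, immune checkpoint and interferon response were called neither way. The block alone added fibroblast (0.0554 without and 0.0474 with it), histone acetylation (0.0595 and 0.0355) and NRF2 and AHR (0.122 and 0.0165). With size factors in place of TMM, 34 of 35 list medians and 369 of 370 list genes kept their sign; the exception among lists was MHC class I presentation, with a median near 0. For the marks, 72 alternatives of the bin counts without the replicate block gave 0 calls; another 10 with the block also gave 0, but 8 pairs allow no p below 0.00781, which 15.6% of the bins would have to reach, so these say nothing about stability. A further 66 alternatives of numbers and lengths gave 0 past the threshold (lowest adjusted p 0.43). The direction was not stable among them: mean covered length of H3K27ac and of H3K4me1 was higher in tumor over all specimens and lower outside the 8 shared numbers. The promoter comparison was not run, and a pseudocount does not apply to count models.

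Other divisions of the same 38 specimens into groups of 18 and 20 were refitted. Chance was not excluded for the 4 RNA genes, since 19 of 100 splits gave as many, with 452 genes in the highest other split. What made that split give so many calls was not tested. Chance was not excluded for the 11 lists either (47 of 100 splits, highest other 19). For the bins of each mark, the real count was 0 and the highest other 0, so all 100 splits gave as many. Simulated 4-fold changes were recovered for 78% of genes and 2-fold changes for 40%, which limits what the RNA depth and spread can show.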

Other observations

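The tests chosen only after the result was seen were those of label exchange, of poor RNA libraries, of equal covered length for H3K27ac and of the relations without N16, N18, N19 and N20; the relations between covered length and gene lists were also chosen after the data were seen. Specimens with much H3K27me3 had less RNA of endothelial, fibroblast and smooth muscle genes, while the relation with collagen and tumor stroma matrix genes was positive and did not pass (r = 0.25, rho = 0.20). Over 38 specimens, the H3K27me3 covered length fell with the mean level of alveolar and adventitial fibroblast genes (Pearson r = -0.56, permutation p = 0.00045, adjusted p = 0.0303; Spearman rho = -0.51, p = 0.00118, adjusted p = 0.0417; r = -0.58 without the 2 specimens farthest from the median) and of smooth muscle and pericyte genes (r = -0.50, p = 0.00174, adjusted p = 0.0435; rho = -0.51, p = 0.00114, adjusted p = 0.0417; r = -0.47 without 2). It rose with glycolysis genes (r = 0.52, p = 0.00163, adjusted p = 0.0435; rho = 0.51, p = 0.00131, adjusted p = 0.0417; r = 0.50 without 2) and with H3K9 methylation genes (r = 0.54, p = 0.00037, adjusted p = 0.0303; rho = 0.51, p = 0.00143, adjusted p = 0.0417; r = 0.44 without 2). Within labels, rho for the fibroblast list was -0.48 (non-neoplastic, n = 20) and -0.62 (tumor, n = 18). Without N16, N18, N19 and N20, which are described next, the r over 34 specimens was -0.48 for fibroblast, -0.49 for smooth muscle, 0.32 for glycolysis (p = 0.0664) and 0.38 for H3K9 methylation genes. Over the remaining 16 non-neoplastic specimens, rho was -0.08 for fibroblast (p = 0.780), -0.30 for smooth muscle (p = 0.254) and 0.16 for H3K9 methylation genes (p = 0.563). The rho of glycolysis genes turned negative there (-0.15, p = 0.586). H3K27ac covered length rose with epithelial keratin and junction genes (r = 0.52, p = 0.00091, adjusted p = 0.0398; rho = 0.52, p = 0.00097, adjusted p = 0.0417; r = 0.42 without 2), with rho = 0.67 in non-neoplastic and 0.20 in tumor specimens; the difference between labels was not tested. These are from a family of 175 relations.

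A few specimens labelled non-neoplastic held high levels of single genes known from squamous or intestinal epithelium; these genes were chosen after their values were seen, and the basal cell list was not called (adjusted p = 0.612). N16 and N18 held KRT5 at 6175 and 3987 CPM and TP63, a squamous lineage factor, at 81.4 and 170 CPM. N19, with NKX2-1 at 1.95 CPM, held CEACAM5 at 6388 CPM and was the closest specimen to N20 in RNA and in H3K27ac. N20 held CEACAM5 at 3839 CPM, CDH17, an intestinal cadherin, at 230 CPM, VIL1, a protein of microvilli, at 255 CPM and LGR5, a receptor of intestinal stem cells, at 258 CPM. GPA33, an antigen of intestinal epithelium, was above the highest tumor specimen in 8 non-neoplastic specimens.

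NKX2-1 RNA in N16, N18 and N20 lay at or below 0.206 CPM, under every tumor-labelled specimen, although NKX2-1 marks lung epithelium. RNA libraries exchanged with specimens of unlike profile are argued against. The H3K27ac profile of each of N16, N18 and N20 was among the 3 best matches of its own RNA profile out of 38. It was the best match for N20 but only in place 3 for N16 and N18, so an exchange between specimens alike in profile is not excluded. The closest specimen to N16 was N18 in RNA and T16 in H3K27ac, and the closest to N18 was N20 in RNA and N14 in H3K27ac. RNA libraries that disagree within a specimen are argued against by a lowest library correlation of 0.9865. Both libraries came from the same specimen, so this value cannot tell whether the RNA of the specimen itself was poor. Tissue labels exchanged between the groups cannot be told apart from correct labels. An exchange within the series needs 3 tumor specimens that look like normal lung, while an exchange with a sample from outside needs none. Of the tumor specimens 1, T6, was above the non-neoplastic median of SFTPC, CAV1 and VWF at once. T6 shares its specimen number with N8 and not with N16, N18 or N20, and an exchange of T6 with N8 was not tested. Tissue of another origin or type may also be present and was not tested.

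H3K27me3 covered length and the endothelial list were inversely related (r = -0.52, p = 0.00052, adjusted p = 0.0303; rho = -0.53, p = 0.00057, adjusted p = 0.0417), with rho = -0.52 in non-neoplastic and -0.70 in tumor specimens. The length also rose with the overlap of the 2 ChIP libraries (r = 0.87, rho = 0.85, p = 1e-05 for each, the smallest the permutations can give), but with that agreement held fixed the rho with the endothelial list was -0.4604 (p = 0.00344), which argues against agreement of the libraries as the whole cause. Specimens extreme in the endothelial list are argued against as the whole cause by r = -0.4903 (p = 0.00182) without the 2 farthest from its median. Those 2 were chosen by the list and not by covered length, so T18 (180 Mb) and T12 (155 Mb) stayed in. Over 34 specimens without N16, N18, N19 and N20, r was -0.48 (p = 0.00305) and rho was -0.43 (p = 0.0133). In the non-neoplastic group the relation rested on these 4, since rho was -0.16 (p = 0.564) in the other 16. The read depth of the ChIP libraries and differences in the mix of cells could each account for the relation and remain open, since depth is unknown and the mix was not measured apart from RNA.

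H3K27ac bins with an unadjusted p under 0.05 leaned to more often marked in tumor specimens (8292 against 861, a difference of 7431). Equal numbers of peaks from every library left the share of such bins at 90.62%, which decides nothing about longer peak lists, since the numbers were alike from the start (means of 89967 and 90157). With equal covered length the share was 64.56% (90.59% as reported), so more covered length in tumor specimens cannot be told apart from other causes and could account for part of the lean. That setting kept only 33.8 Mb of top-ranked peaks per library and tested 51993 bins in place of 125110. The fall in share thus cannot be told apart from an effect of keeping the strongest peaks. Marked bins per specimen still averaged 26422 in tumor and 25611 in non-neoplastic specimens. A chance lean was not excluded: 5 of 100 splits leaned as far, with a difference of 13417 in the highest other split. In specimens outside the 8 shared numbers the share was 60.7%, against 99.8% within them, and a biological difference between the labels stays open.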
